A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

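Transcript levels were measured in 6 samples of rice (Oryza sativa, Japonica group), 3 wild type and 3 dao, each hybridised to its own Affymetrix rice genome array with biotin-labelled target. Samples were grouped and numbered by their titles, which call them biological replicates. The deposited table holds 1 intensity per probe set and array on a linear scale. Its quartiles were near-equal on the 6 arrays, as they would be on arrays brought to a common scale. How background was corrected is not given in the sources used here. The submitters' processing notes name MAS5, without a version or a target value. The values do not settle that method: 7.81% to 9.32% of the values on an array were found exactly on another array, and the value 5.024760917 occurs 1046 times among 344286, which is unusual for a signal computed on each array alone. Detection calls were not used here, so which probe sets lie above background is unknown, and folds of dim genes are uncertain. Per the labels' protocols, RNA was extracted with Trizol.

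Of 57381 probe sets, the 123 controls with names that start with AFFX were left out of the tests. The 64 reporter probe sets stayed in, so the probe sets tested include 8 of them and those past the threshold 1. The table of gene names paired 22436 probe sets with 1 gene and 95 with several and listed none for 34727, so these 34727 are unnamed here. All 17905 genes were matched by Entrez ID to the names of assembly ASM3414082v1, which also gave the order of neighbouring genes, and 2456 of them had a name other than a clone or locus name. The coordinates of that assembly served only to place genes on chromosomes and in that order. A gene with several probe sets was represented by the one with the highest mean signal.

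The deposited intensities were taken to log2 without further scaling, and probe sets with a mean log2 signal under the 40th percentile of the non-control probe sets were left out. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on the mean signal, 2-sided, group as the only term), with Benjamini-Hochberg adjustment. The threshold was an adjusted p of 0.05 together with a 2-fold difference, the limits in the series' own design text, with the adjusted p in place of its q-value, whose method is not given in the sources used here. Before the data were examined, 33 gene lists, the test, the rule for named genes and most alternatives were fixed. A list of auxin amidohydrolases was added before any fold change was computed. Members were found by gene symbol, since the gene table gives few descriptions: the word patterns fixed for each list were turned into symbol patterns before any fold change was computed. Of the lists, 2 had no gene by name and 8 had 1 to 4 measured genes. The 24 lists with at least 5 were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it, adjusted over the 24 lists. Lists may share genes. MADS13, MADS21 and MADS58 were in both the MADS-box and the pistil and carpel lists, and EXPB9 and EXPB10 in both the beta-expansin and the mature pollen lists. RAB16D is named both among the falls and in the dehydrin list.

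The text names DAO, the 10 largest rises and the 10 largest falls among genes past the threshold with every dao array beyond every wild-type array and with a gene name. It also names members from among the 4 per list with the smallest adjusted p, but not all of them. Some left unnamed, as in the aquaporin list, had a smaller adjusted p than members that are named. Among the 10 largest rises 5 places went to genes without a name, and among the 10 largest falls 9, all skipped. In all, 19 genes without a name were passed over for the rises and 68 for the falls. The named rises thus stood at places 2 to 29 among all rises, and the named falls at places 10 to 78 among all falls. A further 18 genes were named after their values were seen.

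The fit was tested on simulated data with the spread of the real arrays and 34355 probe sets. With 6 independent arrays it recovered 17.4% of 46 probe sets changed 2-fold, 59.5% of 42 changed 3-fold, 77.8% of 45 changed 4-fold and 81.0% of 42 changed 6-fold, with 4 calls among 34180 unchanged probe sets. A raised list was found and 0 of 23 unchanged lists were called. The simulated probe sets varied independently of each other, so this does not test list calls where genes move together. With no probe set changed, 0 passed. The third array of each group was then simulated as a mixture of the first and second. The share of the first was set to 0.5 and the technical SD to 0.1 (log2), neither estimated from the real arrays. With no probe set changed, 268 passed and 21.0% had an unadjusted p under 0.05 in limma, against 5.52% with independent arrays. So p-values are too small where the third array is not independent.

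The alternatives were no filter and a filter at the 60th percentile, quantile and median scaling, log2 of the signal plus 32, a constant variance prior, the replicate number as a block, a Storey-type q-value, the adjusted p alone, the mean of a gene's probe sets, and leaving out each array in turn. Leaving out both arrays of each number was added after the data were seen. Figures were drawn with matplotlib 3.10.9, and tables handled with pandas 2.3.3 in Python 3.11.15.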

Results

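The series set anthers of a rice mutant called dao against wild-type anthers. DAO, the dioxygenase for auxin oxidation, turns the auxin indole-3-acetic acid (IAA) into an oxidised form, and the comparison asks which transcripts differ in the anther when this gene is mutated. Total RNA from mature anthers at anthesis, from plants of a japonica variety, was hybridised to the Affymetrix rice genome array, a 1-colour array. There were 3 arrays labelled wild type and 3 labelled dao, numbered 1 to 3 in each group. A free-text line of the labels names three-week-old seedlings, while the titles, source names and tissue fields name mature anthers. The arrays had 57381 probe sets each, with median deposited intensities from 8.80 to 9.31, and the number of arrays limits the precision of every value.

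DAO was measured first, since it is the gene the mutant is named for. Its signal was 480, 883 and 686 on the wild-type arrays and 1551, 1168 and 1391 on the arrays labelled dao, which is a rise of 1.04 on the log2 scale (SE 0.22, n = 3 against 3, adjusted p = 0.0226). The signal on the arrays labelled dao was therefore higher than on the wild-type arrays. The lesion in the mutant and the place of the probes in the transcript are not given in the sources used here, so this value neither checks the labels nor measures the loss of the enzyme. All directions in what follows are for arrays as labelled. The DAO call was lost without wild-type replicate 1 (log2 0.81) or 3 (1.06) and without dao replicate 1 (0.94) or 3 (1.02), and its adjusted p ran from 0.00196 to 0.362 over 20 settings.

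Of 23 measured Aux/IAA genes, which encode repressors of auxin-responsive transcription, 8 rose, 0 fell and 15 did not pass (8 past the threshold also when adjusted over the list alone). IAA20 rose 16.1-fold, from 34.9 ± 23.4 (SD, n = 3) to 515 ± 262 (SD, n = 3), with an adjusted p of 0.00927 (log2 4.01, and 3.37 without wild-type replicate 1). IAA15 rose from 931 ± 88.8 to 2262 ± 200 (log2 1.28, SE 0.11, adjusted p = 0.00237), and IAA10 and IAA18 rose by 1.30 and 1.25 on the log2 scale. IAA31 stood at log2 0.94, under the 2-fold limit, with an adjusted p of 0.00405, and its other probe set at -0.15 (adjusted p = 0.528). The list as a whole was higher than other genes (mean log2 0.89, camera adjusted p = 7.24e-06), and this call was lost with an estimated correlation (adjusted p = 0.422 with an estimated correlation).

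**Figure D1:**
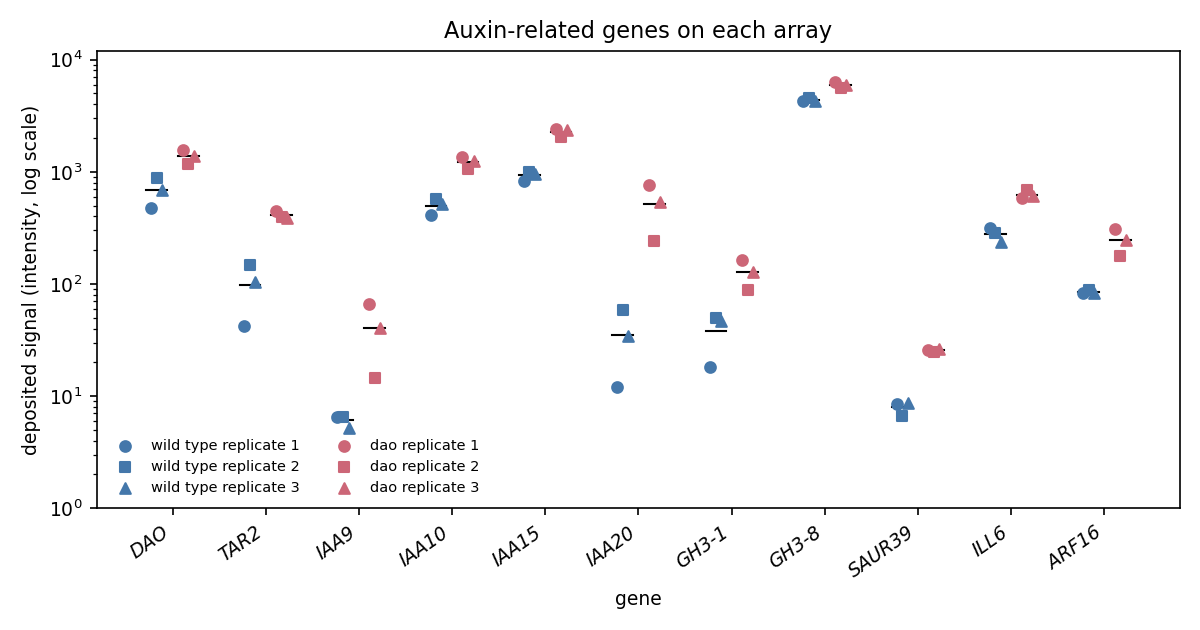
Deposited signal (intensity, log axis) of 11 auxin-related genes on each of the 3 wild-type and 3 dao arrays, with 1 symbol per replicate number and a black bar at the mean of each group. DAO lies at 480 to 883 in wild type and 1168 to 1551 on the dao arrays, and IAA20 at a mean of 34.9 against 515.

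Genes that make, bind or release IAA also included members that rose. TAR2, an aminotransferase of the tryptophan pathway to IAA, rose from 97.8 ± 52.5 to 409 ± 29.0 (SD, n = 3 each; log2 2.24, adjusted p = 0.0148), while YUCCA1, of the step that follows, had a log2 difference of -0.18 (adjusted p = 0.571). Those were the 2 measured genes of auxin synthesis that were found by name. Genes without a name could not enter a list, so this list and the others may be incomplete. Of 9 GH3 genes, whose products join IAA or jasmonate to amino acids, 1 rose, 0 fell and 8 did not pass (1 past when adjusted over the list alone). It was GH3-1, from 38.2 ± 17.5 to 126 ± 37.1 (log2 1.82, adjusted p = 0.0280), and GH3-2 and GH3-8 stood at log2 0.66 and 0.45, under the 2-fold limit. Of 7 amidohydrolases, which free IAA from its conjugates, ILL6 rose (log2 1.17, adjusted p = 0.00397) and 6 did not pass (1 past over the list alone), with IAR and ILL5 at log2 0.97 and 0.98. SAUR39, the measured gene of the small auxin-up RNA list and a repressor of auxin synthesis and transport, rose from 7.92 ± 1.16 to 25.7 ± 0.788 (log2 1.71, adjusted p = 0.00309). Of 17 auxin response factors, transcription factors that bind auxin-responsive promoters, 1 of 2 genes named ARF16 (LOC9270361) rose by 1.50 on the log2 scale and 16 did not pass (1 past over the list alone), with the other ARF16 at log2 0.47 and ARF8 at 0.58. Another probe set of ARF1, which did not pass and was chosen after its value was seen, was past the threshold (log2 1.06, adjusted p = 0.0216). The response factor list was higher than other genes (camera adjusted p = 0.0279, but 0.0601 without wild-type replicate 2 and 0.00618 to 0.482 over 20 settings; adjusted p = 0.482 with an estimated correlation). Neither of the 2 measured auxin transport genes passed, and of the 2 measured genes of the list of DAO and related dioxygenases only DAO did.

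Over all genes, 616 of 15612 tested passed an adjusted p of 0.05 and a 2-fold difference, 493 higher and 123 lower on the arrays labelled dao. In each of the 616 every dao array lay beyond every wild-type array. Such separation was seen in 5850 genes, or 37.5%, where chance gives 10% if the 3 arrays of a group are independent. From replicates 1 and 2 alone it was seen in 43.7%, where chance gives 33.3%. Among probe sets, with or without a gene listed for them, 1157 of 34355 passed, 698 higher and 459 lower. The median log2 difference was 0.11 over genes and -0.01 over probe sets. At least 4-fold differences were found in 77 of the genes that passed, 61 higher and 16 lower. Of 95 genes that passed and had a further tested probe set, 39 had another that passed in the same direction, 56 had none, 15 had another of opposite sign, and 0 had one that passed the opposite way.

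In both groups the third array mostly lay between the other two where these differed. Of the probe sets that differed at least 2-fold between replicates 1 and 2, replicate 3 was between them in 1891 of 1918 in wild type (98.6%) and in 1222 of 1236 on the dao arrays (98.9%). For the other replicates the corresponding share was 3.07% to 31.9%. Over all 34355 tested probe sets, replicate 3 was between the other two in 52.5% in wild type and 55.2% on the dao arrays. The share for the other replicates was then 17.9% to 28.7%. Without both arrays numbered 3, limma called 0 genes, with 1783 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.175, while 1189 genes passed without both arrays numbered 2 and 502 without both numbered 1. Of 63 named genes other than DAO with a call, 43 lost it without wild-type replicate 3, 44 without dao replicate 3, 28 without dao replicate 1, 15 without wild-type replicate 1 and 28 with log2(signal + 32), which shrinks the folds of dim genes, with IAA20, FIL1, TAR2 and GH3-1 among those lost without either array numbered 3 and MADS13 (log2 0.58), SAUR39 (0.53), OPR4 (0.61), GLP2 (-0.43) and IAA9 (0.86) among those lost with log2(signal + 32). The hybridization spike-ins, control RNAs added before hybridisation, were lower on all dao arrays in 27 of 27 probe sets (median log2 -0.38). The 3′ over 5′ signal ratio of ubiquitin was 3.67 ± 0.283 (SD, n = 3) in wild type and 3.00 ± 0.142 (SD, n = 3) on the dao arrays, and that of 1 of 2 GAPDH sets was 92.6 ± 19.9 and 57.9 ± 6.35, without overlap, while the ratios of 5 other sets overlapped. Among those 5, both actin sets and cyclophilin had a higher mean ratio on the dao arrays. The 5′ signals of the GAPDH set without overlap were dim, and signals behind 2 of the overlapping sets went down to 2.73 and 3.74.

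**Figure D2:**
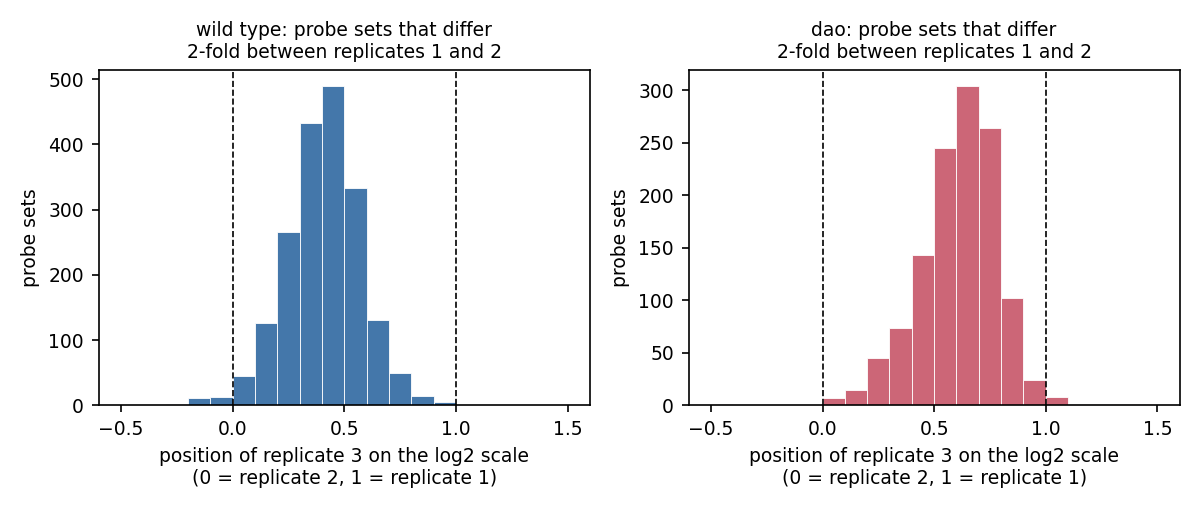
Histograms of the position of replicate 3 between replicate 2 (at 0) and replicate 1 (at 1) on the log2 scale, over probe sets that differ at least 2-fold between replicates 1 and 2, for the wild-type arrays and the arrays labelled dao; bars count probe sets. Of 1918 and 1236 such probe sets, 1891 and 1222 lie between the dashed lines.

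The largest rise among genes with a name was that of YSL12. This gene, of the yellow stripe-like family of metal chelate transporters, rose 17.7-fold, from 33.9 ± 8.46 (SD, n = 3) to 588 ± 30.9 (SD, n = 3; adjusted p = 0.000345). The YABBY transcription factor FIL1, also called YABBY1, rose from 20.3 ± 16.7 to 211 ± 84.8 (log2 3.79, SE 0.75, adjusted p = 0.0192; log2 2.89 without wild-type replicate 1 and 4.48 without 2). The aspartic protease ASP1 and the transcription factor MYB4 rose by 3.17 and 3.01 on the log2 scale, and IAA9 by 2.48 (3.09 without dao replicate 2). MYB4 was at 2.20 without wild-type replicate 1. Its other probe set stood at log2 0.37 (adjusted p = 0.225), and the mean of the 2 at 1.69. The lipid transfer protein gene LTP-2 rose from 127 ± 7.26 to 733 ± 307 and PSK5, which encodes a precursor of the peptide hormone phytosulfokine, from 66.9 ± 22.8 to 355 ± 122.

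The falls were smaller, and those of the genes with a name stood at places 10 to 78 among all falls past the threshold. MGD2, a synthase of the galactolipid of plastid membranes, fell from 77.1 ± 62.4 (SD, n = 3) to 11.4 ± 1.47 (SD, n = 3; log2 -2.39, SE 0.59, adjusted p = 0.0360; log2 -1.74 without wild-type replicate 1 and -3.08 without 2), a call kept in 13 of 20 settings. PPT2, a translocator that exchanges phosphoenolpyruvate and phosphate across the plastid envelope, fell from 247 ± 24.1 to 73.0 ± 22.5 (log2 -1.80, adjusted p = 0.00448). MYBS1, an activator of alpha-amylase genes under sugar starvation, fell from 554 ± 117 to 191 ± 44.8. RAB16D, SAPK10 and CDPK5, which encode a dehydrin, a kinase of abscisic acid signalling and a calcium-dependent kinase, had log2 differences of -1.63, -1.29 and -1.20, with calls kept in 11, 12 and 14 of 20 settings. GLP2, which encodes a germin-like protein, fell from 21.3 ± 5.32 to 7.37 ± 0.792, and cob, the mitochondrial gene for cytochrome b, from 198 ± 16.5 to 84.3 ± 27.2. Of the genes with a name, 114 rose and 13 fell.

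**Figure D3:**
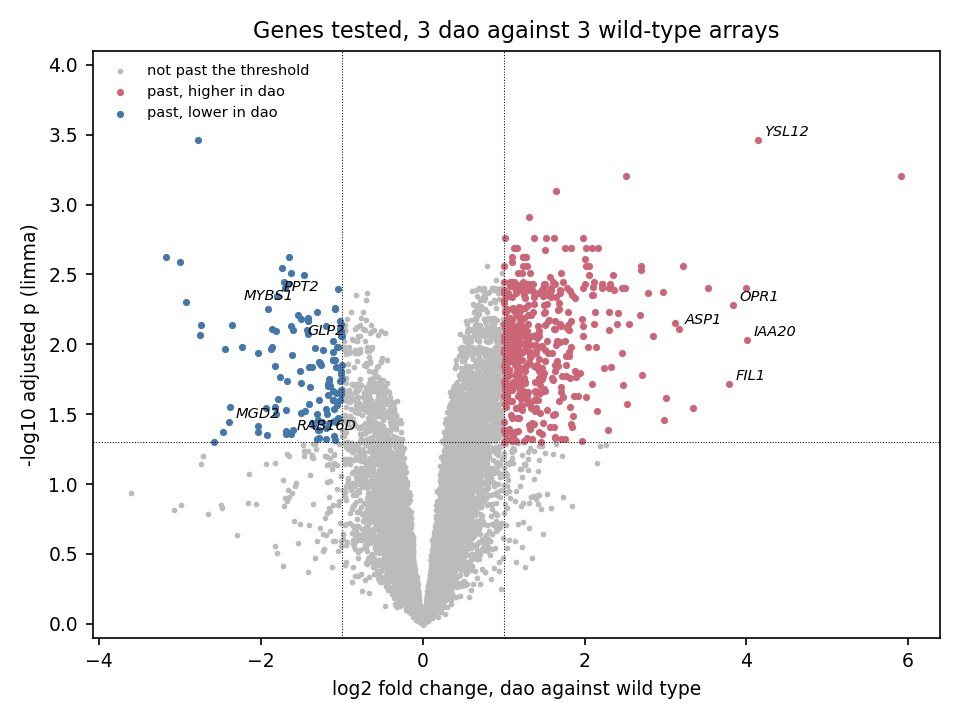
Log2 fold change of each of the 15612 tested genes, dao against wild type (3 arrays each), against -log10 of the limma adjusted p; red points passed and were higher, blue points passed and were lower, and dotted lines mark the limits. Of the 616 genes that passed, 493 lie on the right and 123 on the left.

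Among jasmonate genes, the members that rose were 3 copies of 12-oxophytodienoate reductase. Of 13 measured genes of jasmonate synthesis 3 rose, 0 fell and 10 did not pass (3 past over the list alone). OPR1 rose 14.3-fold, from 17.4 ± 9.46 to 220 ± 48.5 (SD, n = 3 each; adjusted p = 0.00522; log2 3.84, and 3.25 without wild-type replicate 1), and OPR4 and OPR5, near copies that lie beside OPR1 in the order of genes and between which probe sets can cross-hybridise, rose by 1.79 and 1.11 on the log2 scale. OPR7, the rice reductase known to act in jasmonate synthesis, was singled out after its value was seen and had a log2 difference of -0.09 (adjusted p = 0.516). The list had a mean of log2 0.44, a median of -0.09 and a downward camera direction (adjusted p = 0.875). Of 17 genes of the TIFY family, which includes repressors of jasmonate signalling, 2 rose, 1 fell and 14 did not pass (4 past over the list alone). TIFY10C rose by 1.49 on the log2 scale, TIFY11C fell from 936 ± 236 to 438 ± 47.7, TIFY11B stood at -0.69, under the 2-fold limit, and TIFY5, outside the rule for named genes and chosen after its value was seen, rose by 2.15 (1.56 without wild-type replicate 2). Of 7 gibberellin genes 1 passed (1 over the list alone), the gibberellin 20-oxidase GA20OX3, which rose from 948 ± 68.0 to 2224 ± 830 (adjusted p = 0.0284), and none of 3 ethylene synthesis genes passed.

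Of 24 genes of the secondary wall and of lignin, 3 rose, 0 fell and 21 did not pass (4 past over the list alone). They were the 4-coumarate ligases 4CL5, from 9.60 ± 1.87 to 76.9 ± 41.7 (SD, n = 3 each; log2 2.85, adjusted p = 0.00871), and 4CL3 (log2 1.73), and PAL, a phenylalanine ammonia-lyase (log2 1.10), which are the early enzymes of phenylpropanoid synthesis. None of the 4 other probe sets of PAL passed (log2 0.40 to 1.02). The list missed the threshold (camera adjusted p = 0.0565) but passed in 8 of 20 settings (0.00287 to 0.849). Of 10 endoglucanases and xyloglucan transferases, 2 rose and 8 did not pass (3 past over the list alone), with GLU10 and CEL9D at log2 1.25 and 1.02. None of the 10 alpha-expansins (1 over the list alone) or 9 beta-expansins (0 over the list alone) passed. Of 24 genes of sugar transport and invertases, 3 rose, 1 fell and 20 did not pass (4 past over the list alone). The sugar transporters SWEET2B and SWEET15 rose by 1.69 and 1.47 on the log2 scale, SWEET16 had a log2 difference of -1.19 (adjusted p = 0.0473, call kept in 10 of 20 settings), and SWEET1A, outside the rule and chosen after its value was seen, rose by 1.57, with its other probe set at 0.13 (adjusted p = 0.662). Of 22 aquaporins 2 rose, 1 fell and 19 did not pass (3 past over the list alone). PIP1;3 and PIP2;7 rose by 1.55 and 1.41, and PIP2;4 fell from 778 ± 38.0 to 349 ± 195 (adjusted p = 0.0477, call kept in 10 of 20 settings).

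Of 22 MADS-box genes 3 rose, 0 fell and 19 did not pass (3 past over the list alone), and 10 passed on adjusted p alone, all of them higher. MADS13, an ovule identity gene, rose from 6.18 ± 0.600 to 25.3 ± 4.53 (SD, n = 3 each; log2 2.02, adjusted p = 0.00273). The others that rose, MADS17 and MADS6, were outside the rule and chosen after their values were seen, at log2 1.37 and 1.03. MADS4 and MADS7, both floral organ identity genes, stood at log2 0.79 and 0.86 and the stamen and carpel gene MADS3 at 0.78, all under the 2-fold limit. The list was higher than other genes (mean log2 0.50, camera adjusted p = 0.00365; adjusted p = 0.422 with an estimated correlation). Of the 3 measured pistil and carpel markers only MADS13 passed, with MADS58 at log2 0.26 (adjusted p = 0.271) and DL, the carpel identity gene, at -0.09 (adjusted p = 0.756).

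Of the 11 genes of the mature pollen list, 9 are actin-depolymerising factors found by symbol, and the others are EXPB9 and EXPB10. The list thus follows 1 gene family more than it follows pollen. Of the 11 genes, 1 rose, 0 fell and 10 did not pass (1 past over the list alone). It was ADF5, an actin-depolymerising factor, from 97.0 ± 6.30 to 217 ± 29.0 (SD, n = 3 each; adjusted p = 0.00429). On adjusted p alone 3 passed, all higher, with ADF4 at log2 0.67 and ADF2 at 0.33, while ADF9 stood at -0.23 (adjusted p = 0.0552). Of 15 tapetum and exine genes 1 rose and 14 did not pass (0 past over the list alone), namely C6, a lipid transfer protein of the tapetum, at log2 1.63 (adjusted p = 0.0468, call kept in 9 of 20 settings). None of 9 photosynthesis genes passed (0 over the list alone; mean log2 0.46), nor did any of 4 measured endosperm storage protein genes (0 over the list alone). The median signal of the photosynthesis list was 512, 158 and 381 on dao arrays 1, 2 and 3 and 261, 182 and 200 on the wild-type arrays.

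Of 38 heat shock genes 5 rose, 1 fell and 32 did not pass (6 past over the list alone). HSP17.9B rose from 42.2 ± 9.12 to 117 ± 9.42 (SD, n = 3 each; log2 1.49, adjusted p = 0.00522), and HSP18.0 and the heat stress factor HSF6 rose by 1.42 and 1.44 on the log2 scale. Other probe sets of these genes did not pass, at 0.35 (adjusted p = 0.151) and 0.39 (0.0749) for HSP18.0 and 0.54 (0.177) for HSF6, and both calls were lost on the mean of a gene's probe sets. Another probe set of HSP82, which did not pass and was chosen after its value was seen, was past the threshold (log2 1.19). The small heat shock genes HSP17.4 and HSP18.6 rose and the factor HSF-02 fell, all 3 outside the rule and chosen after their values were seen. The HSF-02 call was kept in 10 of 20 settings, and the other probe set of HSP18.6 stood at 0.67, under the 2-fold limit. The list was higher than other genes (mean log2 0.45, camera adjusted p = 0.0128; adjusted p = 0.422 with an estimated correlation). Of 45 genes of the cell cycle, histones and meiosis 0 passed in limma (0 over the list alone), and 5 passed on adjusted p alone, among them CYCB1-3, a mitotic cyclin, at log2 -0.91, CYCD4-1 at 0.86 and the germline argonaute MEL1 at 0.79. That list was lower than other genes (mean log2 -0.11 against a median of 0.11 over all genes; camera adjusted p = 0.0199, but 0.0622 without wild-type replicate 2 and 0.00322 to 0.422 over 20 settings). That call too was lost with an estimated correlation (adjusted p = 0.422 with an estimated correlation).

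None of 23 cytosolic ribosomal protein genes passed (0 over the list alone), with RPL10A and RPS4 at log2 0.99 and 0.91 under the 2-fold limit. Their other probe sets stood at 0.36 and 1.08 without passing, and 1 of 3 further probe sets of RPS3A was past the threshold (log2 1.02, adjusted p = 0.0489). The camera adjusted p of the list was 0.0565, and the list passed in 6 of 20 settings (0.000162 to 0.930). Of 14 peroxidases and glutathione transferases GSTU6 rose (log2 1.20; 1 past over the list alone), another probe set of APX2, which did not pass, was past the threshold (log2 1.10), and of 6 dehydrins and related proteins RAB16D fell (1 past over the list alone). None of 14 defence genes, 8 starch genes or 2 genes of cell death proteases and nucleases passed, and the starch synthase SSII-3 stood at log2 -0.97 (adjusted p = 0.00940), with its other probe set at -0.12 (adjusted p = 0.631). In all, camera called 5 of 24 lists, 4 higher and 1 lower, and 0 with an estimated correlation. Over 20 settings the adjusted p ran from 4.78e-07 to 0.422 for the Aux/IAA list, from 0.000439 to 0.422 for the MADS-box list and from 0.00274 to 0.422 for the heat shock list. The fry rotation test, which asks whether the genes of a list move one way on balance without comparing them with other genes, called 8 lists, among them the Aux/IAA (adjusted p = 0.00518), MADS-box (0.00273), amidohydrolase (0.00518) and aquaporin (0.00440) lists. The median, mean and camera direction differed in sign for 8 lists, namely those of jasmonate synthesis, TIFY, gibberellin, mature pollen, alpha-expansin, starch, dehydrin and defence genes.

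**Figure D4:**
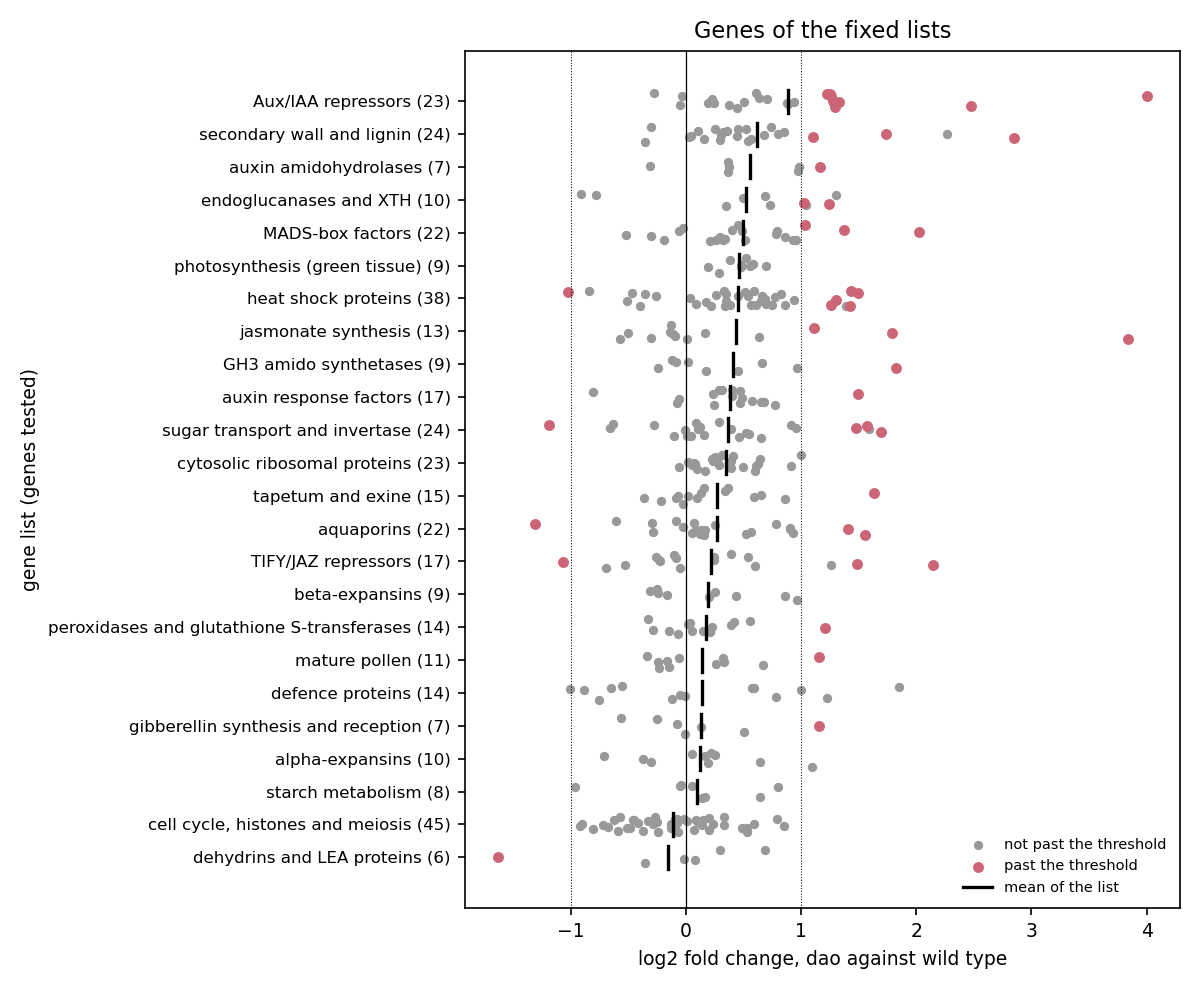
Log2 fold change of each measured gene in the 24 lists with at least 5 tested genes, dao against wild type (3 arrays each), with red points for genes past the threshold and a black bar at the mean of each list. The Aux/IAA list has the highest mean (0.89) and 8 of its 23 genes past the threshold.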

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

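The tests of the third array (an averaged column, pooled RNA, a shared axis) and of the axis within groups, and the fits without both arrays of a number, were chosen only after the result was seen. A control probe set named as a reporter, outside the comparison of rice genes, stood out because its signal was above the wild-type level on every dao array. That signal was 19.6, 4.87 and 8.33 on the wild-type arrays and 54.7, 33.9 and 43.8 on the dao arrays (log2 2.23, SE 0.46, limma adjusted p = 0.0246). The probe set is named RPTR-Os-K01193-1_at, which points to a sequence that was not looked up here. Whether the mutant line carries that sequence is not given in the sources used here. Of 64 reporter probe sets 8 were bright enough to be tested and 1 passed, and the largest difference among the others was 0.60 on the log2 scale in size.

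The third array of each group lay between the others on 98.6% of the wild-type probe sets that differed at least 2-fold between replicates 1 and 2, the lower of the 2 groups' shares. The tables argue against a column averaged from the deposited values, since on the poly-A spike-ins, added to each RNA sample, replicate 3 lay outside the range of replicates 1 and 2 in 65 of 72 comparisons. RNA pooled from replicates 1 and 2 and separate samples that differ along 1 axis, such as the stage of the anther, cannot be told apart: the 98.6% is the pattern itself, which either would give, and no value decides how low the share not between, 1.41% at most, could be for separate samples. The position of replicate 3 on the linear scale, with replicate 2 at 0 and replicate 1 at 1, had medians of 0.307 (1467 probe sets higher on replicate 1) and 0.486 (451 higher on replicate 2) in wild type, and 0.556 (825) and 0.679 (411) on the dao arrays, not 1 common share per group.

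The 616 genes past the threshold came from 1 of the 10 splits of the 6 arrays into 3 and 3, where the highest other split gave 0, and 10 splits are too few for a share under 0.05. A difference in RNA quality cannot be told apart from the genotype. Of the 7 control ratios of 3′ over 5′ signal, 2 separated the groups, both lower on the dao arrays. Of the 5 that overlapped, both actin sets and cyclophilin had higher means on the dao arrays. These were 138 against 110, 55.3 against 38.2 and 4.05 against 3.62 in wild type, so the ratios did not all move the same way. Elongation factor 1 alpha and GAPDH had signals down to 2.73 and 3.74, near the lowest on the arrays, and could not show a difference. Linked background, segments that differ between the parents of the lines, is left open by the neighbour test. Of 615 placed genes, 228 had another called gene among the 5 nearest measured genes on either side. Chance gave 203 (permutation p = 0.0481, 10000 draws), so called genes lay together somewhat more often than by chance. Tandem copies such as OPR1, OPR4 and OPR5 add to the 228, so the test cannot tell them from linked segments. Taken separately, neither the 493 genes that rose (permutation p = 0.0743) nor the 122 placed genes that fell (permutation p = 0.294) passed. A difference in anther stage or make-up is left open by the axis test: across genes the difference of dao from wild type over replicates 1 and 2 correlated at r = 0.312 with that of wild-type replicate 2 from 1 and at 0.260 with that of dao replicate 1 from 2, but shared arrays alone could give up to 0.576 and 0.469, and the 2 differences within groups, which share no array, correlated at -0.222. These explanations and an effect of the dao mutation itself, which the design names, stay open together.

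The labels name both anther and seedling. The median signal of the mature pollen list was above that of the photosynthesis list on 6 of 6 arrays, the outcome expected without seedling RNA. But signals of different probe sets cannot be compared with each other, and no array of known tissue is at hand. Of the 11 genes of the pollen list, moreover, 9 are actin-depolymerising factors. That test is void. Over the 6 arrays the floral organ identity genes MADS4 and MADS7 stood at 831 to 1492 and 710 to 1485, and MADS3 at 164 to 338. EXPB9 of the pollen list stood at 11242 to 13036. The upper quartiles of the arrays were 49.0 to 55.2. These values, chosen after they were seen, argue against arrays of seedling RNA alone. The photosynthesis list medians also lay above those quartiles, so a share of other tissue is not excluded.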

How the results depend on the processing

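The fits without both arrays of a number were chosen after the data were seen. Genes past the threshold, 616 as reported, numbered 221 with log2(signal + 32), 2416 on adjusted p alone, and 191 to 924 without 1 array (191 without wild-type replicate 3, 191 without dao replicate 3, 378 without dao replicate 1, 924 without dao replicate 2). Probe sets, 1157 as reported, numbered 405, 3396 and 278 to 1679 in the same order. The offset of 32 shrinks the folds of dim genes by construction, so how far dim signals lie above background limits these counts; it ended 28 of the 63 calls of named genes other than DAO. Without both arrays numbered 3 limma called 0 genes and 0 probe sets (1783 genes at an unadjusted p under 0.05), and without both numbered 2 it called 1189 genes, 597 of them among the 616, and 2238 probe sets. Without both numbered 1 it called 502 genes, but p-values are too small where the third array is not independent, so whether 4 independent arrays are too few stays open. Under the other 8 alternatives and without wild-type replicate 1 or 2, counts of genes lay between 546 and 827. DAO kept its direction, at log2 0.81 to 1.25 without 1 array, 1.05 without both numbered 3 and 0.71 without both numbered 1, where its call ended. Of 24 lists, 5 as reported, 0 were called with an estimated correlation, 8 by fry, 8 without a filter, 8 with quantile scaling and 5 to 8 without 1 array. For other values the cause was not tested. Of 90 other named genes 63 had a call, all lost without both arrays numbered 3, where 2 others changed sign, YUCCA1 to log2 0.067 and DL to 0.0046; DL also did so without both numbered 1, at 0.047. Neither had passed, and no other named gene changed sign. The replicate block gave 619 genes and 1136 probe sets and ended the call of the auxin response factor list (adjusted p = 0.0647; range 0.00618 to 0.482 over 20 settings), while that of the ribosomal list was gained (0.00298; range 0.000162 to 0.930). Whether the numbers pair the samples is not settled. Deviations from the group mean of same-numbered arrays correlated at 0.232, 0.199 and 0.0417 across tested genes. Those of wild-type replicate 1 with dao replicate 2 correlated at -0.219, and those of wild-type replicate 2 with dao replicate 1 at -0.198. Wild-type replicate 3 correlated best with dao replicate 2 (0.0904).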

Other observations

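The genes in this paragraph were chosen after their values were seen, from those past the threshold. Of 4 measured cytokinin oxidases, which break down cytokinin, 2 rose and 2 did not pass. CKX11 rose from 148 ± 14.8 to 456 ± 35.5 (SD, n = 3 each; log2 1.62, adjusted p = 0.00175), and CKX4 from 21.1 ± 3.63 to 62.7 ± 4.84 (log2 1.58, adjusted p = 0.00397). Of 7 response regulators, RR9, of the kind that cytokinin induces, rose by 1.04 on the log2 scale. The brassinosteroid receptor gene BRI1 rose by 1.19 and EUI, whose product inactivates gibberellins, by 1.17. Of 4 SPX genes and 7 phosphate transporters, SPX3 and PT8 rose by 1.40 and 1.38. Of 13 yellow stripe-like transporters YSL12 and YSL9 rose, YSL9 by 1.10, and 11 did not pass.

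Among genes without a name, LOC4331398 rose from 5.93 ± 2.61 (SD, n = 3) to 339 ± 61.3 (SD, n = 3) and LOC4343713 from 6.10 ± 0.855 to 111 ± 64.1. Their wild-type signals lie below the array medians of 8.93 to 9.31, so the size of these rises is uncertain. LOC4326253 fell from 435 ± 94.3 to 55.4 ± 18.8 and LOC4339187 from 49.8 ± 7.17 to 5.72 ± 2.08, where the same holds for the dao signal. Probe sets with 1 gene listed and the others moved apart. Of 18330 tested probe sets with 1 gene listed, 541 were past the threshold and higher and 146 lower, with a median log2 difference of 0.10. Of 16025 tested with several genes or none listed, 157 were higher and 313 lower, with a median of -0.09. The poly-A spike-ins separated the groups in 0 of 36 probe sets (median log2 -0.15).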
